A study of Homo sapiens with 8 samples.

How the data were processed

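RNA from 8 liver metastases of the human melanoma line A375 in mice, 4 under anti-miR-182 and 4 under control treatment, was measured on 1 Affymetrix array each. Per the labels' protocols, total RNA was purified on columns and 100 ng was labelled with a 3 prime IVT kit. The deposited table holds 1 intensity per probe set and array. Per the submitters' processing notes the authors used RMA, which corrects background, normalizes probes by quantiles and summarizes each probe set; its version is not given in the sources used here. The deposited intensity values lie on a linear scale, between 6.00 and 28136, and log2 was taken before any test, as had been foreseen for that case. No detection calls, batches or scan dates were used here, so signal over background was not assessed.

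Probe sets were named through the platform's annotation table, with symbols looked up in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Of 54613 probe sets tested (62 control probe sets were set aside), 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none. A gene was represented by its brightest probe set with 1 symbol, giving 19775 genes. Of 10523 genes with more than 1 probe set, 252 had probe sets in both directions at an unadjusted p under 0.05. The arrays carry human probes, and what share of the signal came from mouse RNA was not analysed here.

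Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, anti-miR-182 minus control, with no covariate, and Benjamini-Hochberg adjustment over all 54613 probe sets. No filter on dim probe sets was applied. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the 22 lists. camera sets a list against all other genes, whereas fry asks whether a list's genes move one way on balance. The median of each list was also ranked among 10000 random lists matched on mean log2 intensity in 20 bins. Values per array were compared with an exact two-sided permutation test, and 8 array measures were adjusted as a family. Array controls were the means or ratios of the manufacturer's control probe sets, 9 of them for the bacterial hybridization controls. Figures were drawn with matplotlib 3.10.9.

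The 22 lists (490 genes), the tests and the rule for naming genes were set before the data were examined. The rule took the largest differences past the threshold on each side; as none passed, it gave the 6 genes with the smallest p on each side among those brighter than the median probe set, then up to 4 members of each list with the smallest p, and 10 reported miR-182 targets. Further lists of liver genes, host blood and sinusoid genes, nuclear-retained transcripts, fibroblast genes, cancer-testis antigens and genes of other tissues were written after the arrays were examined and before each was tested. A planned test of genes with miR-182 seed sites was not run, since 3 prime UTR sequences were not used here.

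The steps were tested on simulated data with the real means and variances of the 54613 probe sets: with 4 arrays per group, 65 of 100 2-fold changes and 96 of 100 4-fold changes were recovered, all with the right sign, with 4 false calls. camera called 5 of 5 shifted and 1 of 20 unshifted lists simulated from the 19775 genes. The simulated noise was independent between probe sets, with no array-wide shift and no outlying array. These rates therefore need not hold on the real arrays, where genes of a list were correlated. Alternatives were an intensity trend with robust eBayes, only probe sets brighter than the median, quantile normalization again, median centring, array weights, the replicate number as a block, leaving out each array, other thresholds, and the mean of all probe sets of a gene. Cyclic loess, leaving out 2 arrays together, the ranks among random lists and the comparison with genes of other tissues were added after the data were seen.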

Results

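Liver metastases of A375 cells, an established human melanoma line, grown in mice were profiled on an Affymetrix expression array, of which 54613 probe sets were tested. Of the 8 samples, 4 came from metastases exposed to an anti-miR against miR-182 and 4 from control-treated metastases. An anti-miR is a short oligonucleotide that pairs with a microRNA and blocks it. Dosing was intraperitoneal, 2 times a week for 4 weeks. The single comparison, anti-miR-182 against control, asked which genes and pathways differed with the treatment. The labels number the samples of each group from 1 to 4 but do not say that they came from separate animals, so p-values rest on the spread between these samples, whatever its source. The median log2 intensity per array was 4.74 ± 0.01 (SD, n = 4) in the controls and 4.82 ± 0.06 in the treated group. The number of arrays limits the precision, and an exact test of 4 against 4 cannot give a p below 0.0286.

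No single gene passed the threshold. The genes with the smallest p included a ubiquitin ligase and a complement chain on the higher side, and Golgi complex subunits and the ribosomal RNA precursor on the lower side. Values are log2 differences, anti-miR-182 minus control, ± SE of the fit with n = 4 arrays per group. Among genes brighter than the median probe set, the smallest p on the higher side belonged to IGHD (0.89 ± 0.12), the constant region of immunoglobulin D, RNF5 (1.40 ± 0.19), a ubiquitin ligase of the endoplasmic reticulum, and KIF12 (0.66 ± 0.09), a kinesin. They were followed by PSPN (0.79 ± 0.12), a neurotrophic factor, XAGE3 (0.58 ± 0.09), a cancer-testis gene, and C1QA (0.64 ± 0.10), a complement chain made by macrophages. Apart from RNF5, at a mean log2 intensity of 7.71, these genes were dim, from 5.18 (C1QA) to 5.63 (KIF12). Probe sets between 5 and 6 in general read higher on the treated arrays, by a median of 0.09. On the lower side stood COG3 (-0.90 ± 0.11) and COG5 (-0.72 ± 0.11), subunits of the conserved oligomeric Golgi complex, and HAUS2 (-0.87 ± 0.11), a subunit of the augmin complex of the spindle. The others were BAGE2 (-1.02 ± 0.14), a melanoma antigen gene, RNA45SN5 (-1.93 ± 0.27), a ribosomal RNA precursor, and RUSC1-AS1 (-1.45 ± 0.22), an antisense RNA. COG3, COG5, HAUS2 and RNA45SN5 were brighter, from 6.60 (COG3) to 8.78 (RNA45SN5), where probe sets in general read lower on the treated arrays. BAGE2 (5.77) and RUSC1-AS1 (5.52) were dim and went against the general rise of dim probe sets. In each of these 12 genes the 4 treated arrays lay wholly on 1 side of the 4 controls, and each had an adjusted p of 0.102 in limma. That describes the brightest probe set of each gene. At an unadjusted p under 0.05, 1 of 2 probe sets of COG3, 1 of 3 of COG5, 2 of 4 of HAUS2 and 1 of 2 of RUSC1-AS1 were lower. On the higher side, 1 of 2 of PSPN and 3 of 5 of IGHD were higher.

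limma called 0 of 54613 probe sets and 0 of 19775 genes at an adjusted p under 0.05, and 0 of either at 0.1. The smallest adjusted p was 0.102, shared by 556 probe sets. At an unadjusted p under 0.05 there were 13530 probe sets, 7962 higher and 5568 lower, where 2731 would be expected by chance, and 4764 genes, 3234 higher and 1530 lower. All 4 treated arrays lay above all controls for 6729 probe sets and below them for 2884, together 17.6% of probe sets against 2.86% by chance. With limma's array weights, which gave anti-miR-182 replicate 1 a weight of 0.221, 389 probe sets (182 higher, 207 lower) and 124 genes (98 higher, 26 lower) passed at 0.05, among them TTR, F2, ALAS2 and all 12 genes above. Centring each array on its median turned the split at an unadjusted p under 0.05 to 4695 higher and 7542 lower, and cyclic loess turned it to 3635 and 5997.

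Genes that the literature names as miR-182 targets did not move together. Of the 31 measured members of that list, 5 were higher and 4 lower at an unadjusted p under 0.05, and 0 passed, whether adjusted over all probe sets or adjusted over the list alone. FOXO3, a forkhead transcription factor, measured -0.64 ± 0.21 (adjusted p = 0.133 in limma), with all 4 treated arrays below the controls. Its relative FOXO1 measured -0.01 ± 0.32 and MITF, the master regulator of melanocytes, -0.27 ± 0.32, in both cases within the spread between arrays. Both changed sign when 1 array was left out, to 0.24 and 0.08 without control replicate 2. Higher values were found for the retinoic acid receptor RARG (0.41 ± 0.10), the actin-binding protein MTSS1 (0.69 ± 0.28), cyclin CCND2 (0.64 ± 0.24) and the matrix protein THBS1 (1.12 ± 0.45), as were lower ones for CREB1 (-0.40 ± 0.13) and RGS17 (-0.66 ± 0.22). Leaving out 1 array moved MTSS1 to 0.40 (without anti-miR-182 replicate 1), CCND2 to 0.40 and THBS1 to 0.63 (both without control replicate 4). These 6 genes had adjusted p from 0.108 to 0.180 in limma. CYLD (-0.33 ± 0.15), ADCY6 (-0.32 ± 0.25), CTTN (-0.26 ± 0.18), RECK (-0.15 ± 0.11) and BCL2 (-0.10 ± 0.26) all had larger p. Without anti-miR-182 replicate 1, CYLD measured -0.20, ADCY6 -0.06, CTTN -0.14 and BCL2 0.20, and without control replicate 3 RECK measured -0.23. These values are those of the brightest probe set, and other probe sets of a gene differed in places. At an unadjusted p under 0.05, 1 of the 3 probe sets of FOXO1 was higher (0.45), 2 of 5 of RECK were lower (down to -0.79), 1 of 5 of CTTN was lower (-1.09), 1 of 7 of CYLD was lower (-0.53), and of the 4 of BCL2 1 was higher and 1 lower. The list's median was -0.15 (camera adjusted p = 0.122), but -0.07 after quantile normalization again.

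**Figure D1:**
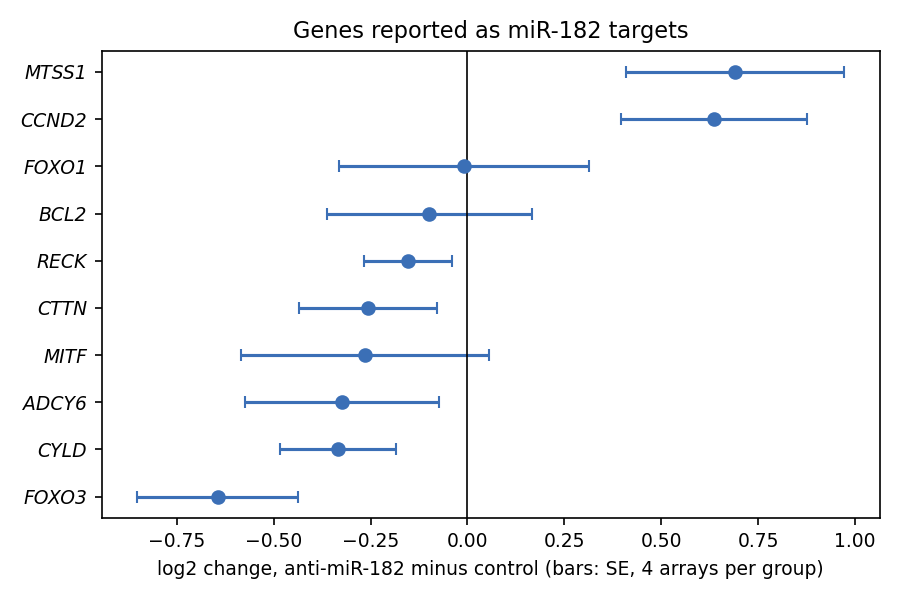
Log2 difference (anti-miR-182 minus control, horizontal axis) of the 10 genes fixed beforehand as reported miR-182 targets; points are limma estimates and bars their SE with n = 4 arrays per group. MTSS1 (0.69) and CCND2 (0.64) lie to the right and FOXO3 (-0.64) to the left, and none passed an adjusted p of 0.05.

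Genes downstream of FOXO factors had a median of -0.22 over 27 members (camera adjusted p = 0.118). That median stood at percentile 0.96 of random lists of like brightness. In the list, SOD2, the mitochondrial superoxide dismutase, measured -0.51 ± 0.18 and CDKN1A, the cell cycle inhibitor p21, 0.68 ± 0.29. The FOXO list's median was -0.10 after cyclic loess, -0.05 after quantile normalization again and -0.06 without control replicate 4 and anti-miR-182 replicate 1. Melanocyte lineage genes gave a median of 0.20 and a mean of -0.04 over 21 members, which differ in sign (camera adjusted p = 0.759). That median was 0.08 after cyclic loess and 0.00 without control replicate 4 and anti-miR-182 replicate 1. The transporter SLC45A2 (0.61 ± 0.18), the transcription factor IRF4 (0.57 ± 0.20), the channel TRPM1 (0.31 ± 0.11) and tyrosinase TYR (0.34 ± 0.12) had the smallest p in it. Of its 21 members 5 were higher and 0 lower at an unadjusted p under 0.05, against 24.1% of all genes in either direction. These 4 genes were dim, with mean log2 intensities from 3.50 (TRPM1) to 4.95 (IRF4), where probe sets in general read higher on the treated arrays. IRF4 measured 0.36 without anti-miR-182 replicate 1. In both lists 0 members passed when adjusted over the list alone.

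Hepatocyte markers rose as a list with camera's preset correlation (adjusted p = 3.85e-05), a call lost at an adjusted p = 0.416 with an estimated correlation. Of its 24 measured genes, 10 were higher and 0 lower when adjusted over the list alone, and 0 passed over all probe sets; 10 had all 4 treated arrays above all controls. The median difference was 0.37, and 0.22 after cyclic loess. TTR, the carrier of thyroid hormone and retinol, measured 1.62 ± 0.26, a 3.07-fold higher intensity, from 9.03 ± 0.39 (SD, n = 4) in the controls to 10.65 ± 0.47 in the treated arrays. Prothrombin F2 measured 0.92 ± 0.17, and the lipoproteins APOA1 and APOA2 0.56 ± 0.11 and 0.81 ± 0.17. ALB, the most abundant liver transcript and chosen here after its value was seen, measured 0.20 ± 0.18 and stayed dim, at 3.81 in the treated arrays; without anti-miR-182 replicate 1 its difference was 0.03. fry gave the list an adjusted p of 0.0202. A further set of 66 measured genes of other tissues (retina, pancreas, muscle, testis and the like), written down after the arrays were examined but before its test, had a median of 0.28, with 27 members higher and 0 lower at an unadjusted p under 0.05. Measured against those genes within each array, the hepatocyte list stood 0.16 higher in the treated group, with no overlap (two-sided exact permutation p = 0.0286, adjusted p = 0.171 over 6 lists). As 0.0286 is the smallest p this test can give, 1 list alone could not pass 0.05 after that adjustment.

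Erythroid markers also rose as a list with the preset correlation (camera adjusted p = 0.0248, 4 genes measured, median 0.60), a call lost at an adjusted p = 0.416 with an estimated correlation. The heme synthesis enzyme ALAS2 measured 0.65 ± 0.12, the globin HBB 0.75 ± 0.23 and the anion exchanger SLC4A1 0.56 ± 0.20, all 3 higher when adjusted over the list alone; AHSP, a globin chaperone, measured 0.21 ± 0.14 and did not pass. Against the genes of other tissues the list stood 0.24 higher, with overlap (exact permutation p = 0.0571, adjusted p = 0.171). Without anti-miR-182 replicate 1, SLC4A1 measured 0.36, and without anti-miR-182 replicate 2 AHSP measured 0.10. The call was also lost without control replicate 3 (0.0520) or anti-miR-182 replicate 3 (0.0584).

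Other host cell markers did not pass with camera on all arrays, though some did in other settings; each of these 4 lists had an adjusted p = 0.416 with an estimated correlation. Endothelial markers had a median of 0.36 over 15 genes (camera adjusted p = 0.0693, fry 0.0340), with CLEC14A at 0.44 ± 0.11, EGFL7 at 0.37 ± 0.11, TEK at 0.38 ± 0.14 and VWF at 0.36 ± 0.13; 6 members were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Camera called the list without control replicate 1 (0.0392), control replicate 2 (0.0300) or anti-miR-182 replicate 4 (0.0394), and with the mean of all probe sets (0.0335), but not with an estimated correlation (adjusted p = 0.416). Its median stood at percentile 99.57 of random lists of like brightness on all arrays and was 0.21 after cyclic loess. Against the genes of other tissues the list differed by -0.03 (exact permutation p = 0.771). Leukocyte and macrophage markers had a median of 0.22 over 18 genes (camera adjusted p = 0.0694), including the scavenger receptor CD163 at 0.45 ± 0.16, the complement chain C1QC at 0.36 ± 0.13 and the T cell receptor chain CD3E at 0.48 ± 0.15. That list's median stood at percentile 69.95 of random lists of like brightness. Of its members 1, C1QA, was higher when adjusted over the list alone, and against the genes of other tissues the list differed by -0.08 (exact permutation p = 0.429). Camera did not call it with an estimated correlation (adjusted p = 0.416) and called it in 6 settings, with adjusted p from 0.0206 without control replicate 1 to 0.0369 without anti-miR-182 replicate 4; the others were leaving out control replicate 2 (0.0295), genes brighter than the median probe set (0.0282), the mean of all probe sets (0.0335) and the replicate block (0.0244). Bile duct and neural markers had a median of 0.33 over 7 genes (adjusted p = 0.159), with keratin KRT19 at 0.37 ± 0.11, myelin protein MBP at 0.33 ± 0.10, GFAP at 0.34 ± 0.11 and SOX9 at -0.35 ± 0.20; 3 members were higher when adjusted over the list alone. SOX9 measured -0.22 without anti-miR-182 replicate 1. The list's median stood at percentile 97.67 of random lists of like brightness on all arrays and was 0.17 after cyclic loess. Fibroblast and stellate cell markers had a median of -0.67 over 14 genes (adjusted p = 0.111), at percentile 0 of random lists of like brightness. Control replicate 4 averaged 8.72 over this list against 7.27 to 7.32 in the other controls, and without it and anti-miR-182 replicate 1 the median was -0.06. Camera called the list without control replicate 2 (0.0263) and with the replicate block (0.0491), but not with an estimated correlation (adjusted p = 0.416). RGS5, a pericyte gene, measured -2.60 ± 1.06, but -1.41 without control replicate 2. COL3A1 measured -0.89 ± 0.51, but -0.35 without control replicate 4, and 1 of its 5 probe sets was higher and 0 lower at an unadjusted p under 0.05. PDGFRB measured -0.46 ± 0.27, but -0.19 without anti-miR-182 replicate 1, while desmin DES measured 0.35 ± 0.10; 0 members passed when adjusted over the list alone.

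**Figure D2:**
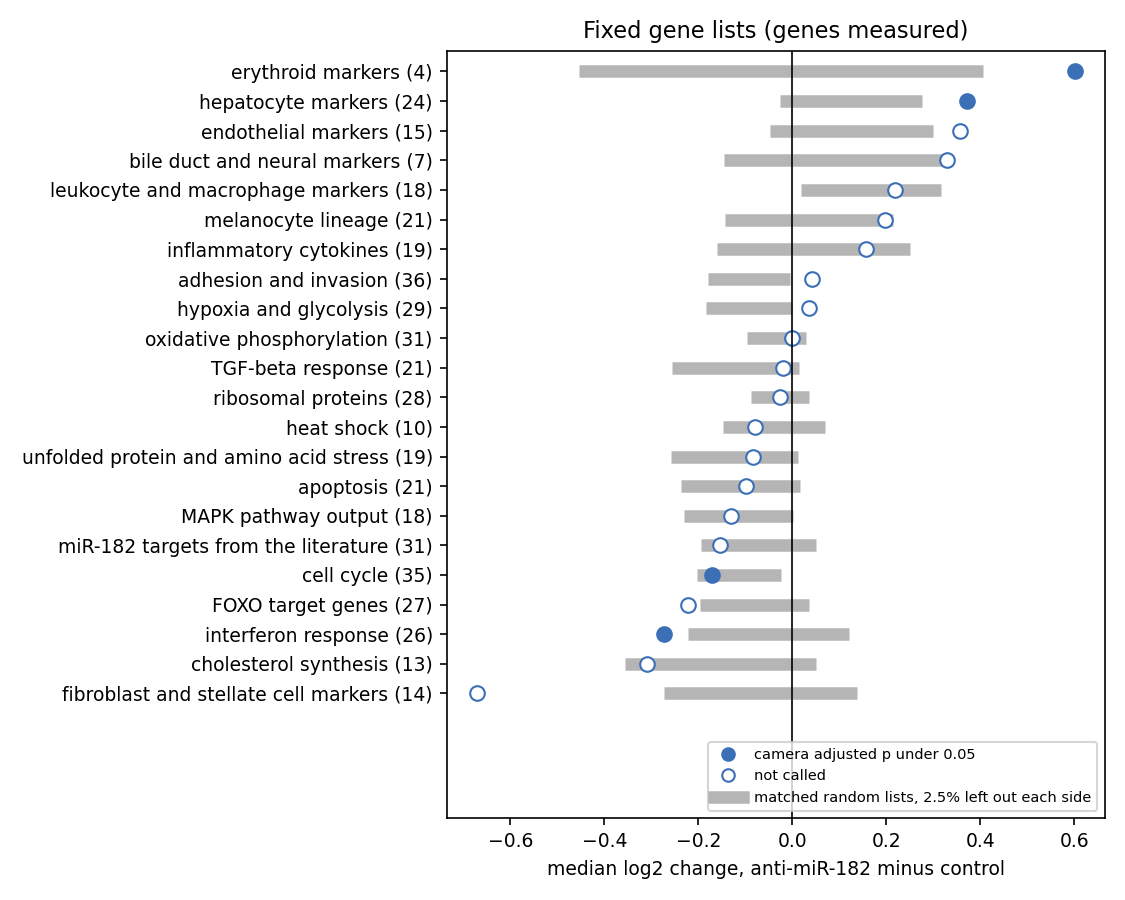
Median log2 difference (anti-miR-182 minus control, horizontal axis) of the 22 fixed gene lists, with the number of measured genes; filled points passed camera at an adjusted p under 0.05, open points did not, and grey bars span the medians of 10000 random lists of like brightness, leaving out 2.5% on each side. Of the called lists, hepatocyte (0.37) and erythroid (0.60) markers lie to the right of their bars, interferon genes (-0.27) to the left, and cell cycle genes (-0.17) within the bar. Of the lists not called, endothelial (0.36), bile duct and neural (0.33), adhesion (0.04) and hypoxia (0.04) genes also lie to the right. Fibroblast markers (-0.67) and FOXO targets (-0.22) lie to the left.

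Cell cycle genes fell as a list with the preset correlation (camera adjusted p = 0.00174, median -0.17, 28 of 35 genes negative), a call lost at an adjusted p = 0.416 with an estimated correlation. Few members stood out: 0 were higher and 4 lower at an unadjusted p under 0.05, and 1, the spindle checkpoint kinase BUB1, was lower when adjusted over the list alone. BUB1 measured -0.50 ± 0.10 on its brightest probe set, whereas 2 of its 5 probe sets were higher at an unadjusted p under 0.05. The proliferation antigen MKI67 measured -0.43 ± 0.16, the kinetochore protein CENPF -0.81 ± 0.32 and NUSAP1, a spindle protein, -0.42 ± 0.17, the last -0.27 without control replicate 4. The call was also lost with fry (0.372), among genes brighter than the median probe set (0.145), after quantile normalization again (0.0858) and after cyclic loess (0.251). Its median was -0.03 after quantile normalization again, -0.06 after cyclic loess and -0.05 without control replicate 4 and anti-miR-182 replicate 1. On all arrays it lay at percentile 9.65 of random lists of like brightness.

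Interferon response genes fell as a list as well with the preset correlation (camera adjusted p = 0.0177, median -0.27, 20 of 26 genes negative), a call lost at an adjusted p = 0.416 with an estimated correlation. There were 0 higher and 2 lower at an unadjusted p under 0.05 and 0 passing when adjusted over the list alone. IFIT3 measured -0.58 ± 0.19, IFIT2 -0.60 ± 0.29, IFI44L -0.66 ± 0.32 and XAF1 -0.41 ± 0.16; the first 3 are induced by type I interferon. IFIT2 measured -0.39 without control replicate 2. Of the 2 probe sets of IFIT2, 1 was higher at an unadjusted p under 0.05 (0.41), and 1 of the 3 probe sets of XAF1 was higher at an unadjusted p under 0.05. The call was also lost with fry (0.489), among genes brighter than the median probe set (0.277), and without control replicate 3 (0.0791), anti-miR-182 replicate 1 (0.0606) or anti-miR-182 replicate 3 (0.0584). Leaving out control replicate 4 and anti-miR-182 replicate 1 together gave 0.113 and a median of -0.06. The median was -0.05 after quantile normalization again and -0.16 after cyclic loess.

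**Figure D3:**
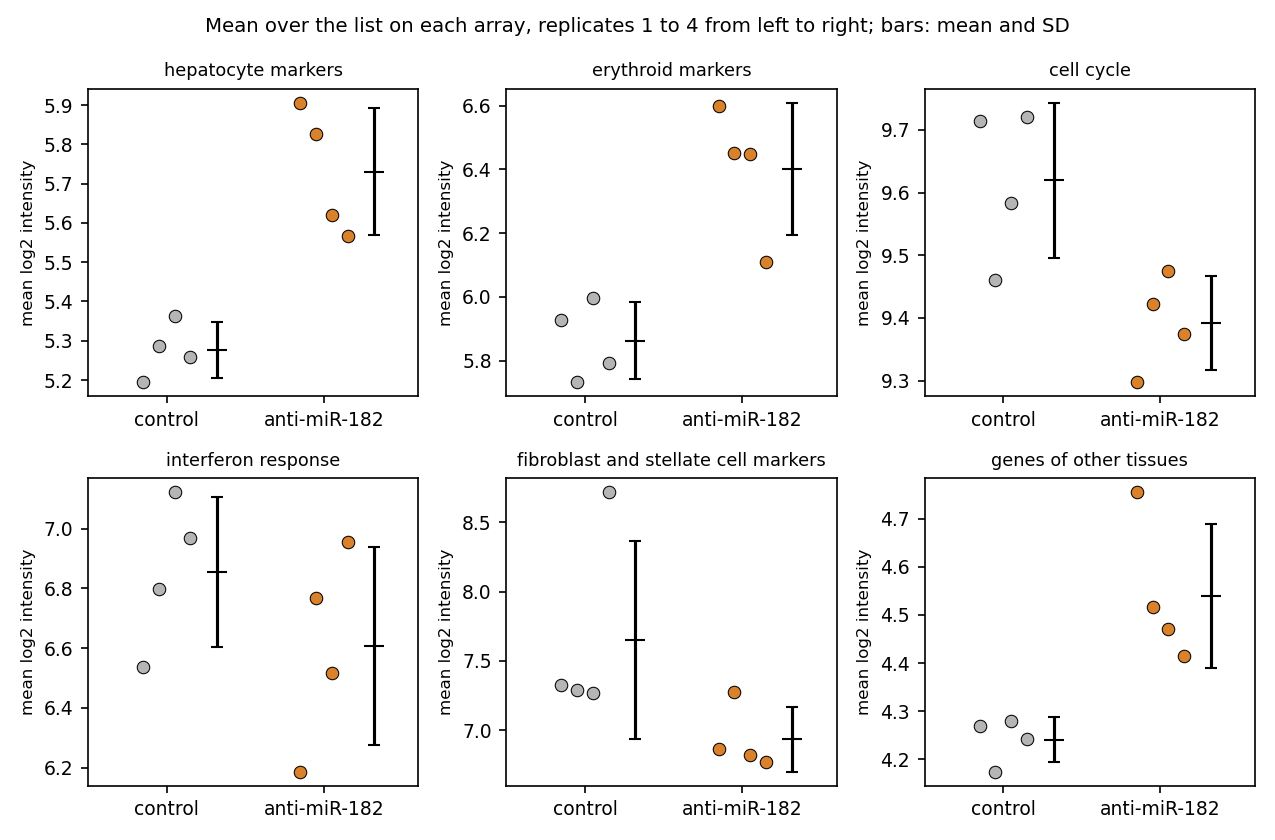
Mean log2 intensity over 5 fixed lists and over the genes of other tissues on each array (vertical axis), grey for control and orange for anti-miR-182, replicates 1 to 4 from left to right within a group, with group mean and SD beside the points. Hepatocyte markers averaged 5.28 in the controls and 5.73 in the treated arrays with no overlap, and control replicate 4 stands alone at 8.72 for fibroblast and stellate cell markers.

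The remaining lists did not pass. Among inflammatory cytokines (19 genes, median 0.16, camera adjusted p = 0.750), IL6 measured 1.10 ± 0.25 and was the 1 member to pass when adjusted over the list alone. The chemokine CCL5 measured 0.78 ± 0.23, IL1B 0.47 ± 0.21 and CXCL8 0.47 ± 0.23, the last 0.29 without anti-miR-182 replicate 3. The cytokine median was 0.06 and the cholesterol median -0.17 after cyclic loess, the latter -0.07 after quantile normalization again. Cholesterol synthesis genes (13 genes, median -0.31, adjusted p = 0.158) went both ways. The transcription factor SREBF2 measured 0.51 ± 0.12, the sterol carrier STARD4 -0.61 ± 0.17 and the desaturase SC5D -0.84 ± 0.26, these 3 passing when adjusted over the list alone. Probe sets disagreed for 2 of them: of the 3 of SREBF2 only 1 was above 0, the lowest at -0.30. Of the 2 of SC5D 1 was above 0, at 0.15. MVD measured 0.40 ± 0.14. In the unfolded protein and amino acid stress list (19 genes, median -0.08, adjusted p = 0.272), CHAC1, a glutathione-degrading enzyme, measured 0.57 ± 0.12 and passed when adjusted over the list alone, against EDEM1 at -0.40 ± 0.16 and SEL1L at -0.43 ± 0.19.

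Adhesion and invasion genes had a median of 0.04 and a mean of -0.01 over 36 members (camera adjusted p = 0.535), with integrin ITGA4 at -0.77 ± 0.32 and cadherin CDH11 at -0.86 ± 0.44, or -0.44 without anti-miR-182 replicate 4. Hypoxia and glycolysis genes had a median of 0.04 and a mean of 0.01 over 29 members (adjusted p = 0.503). For both lists camera gave the direction down, opposite to the median, while the medians stood at percentiles 99.86 and 99.81 of random lists of like brightness. Camera called the hypoxia list without control replicate 4 (0.0194) and without it and anti-miR-182 replicate 1 (0.0178), but not with an estimated correlation (adjusted p = 0.839). KDM3A, a histone demethylase of that list, measured -0.49 ± 0.19. Apoptosis genes (21 genes, median -0.10, adjusted p = 0.158) included APAF1, the core of the apoptosome, at -0.49 ± 0.18 and the caspase inhibitor XIAP at -0.39 ± 0.16, or -0.24 without anti-miR-182 replicate 2; 1 of the 3 probe sets of APAF1 was higher at an unadjusted p under 0.05. TGF-beta response genes (21 genes, median -0.02, adjusted p = 0.497) included ID1 at -0.49 ± 0.22, and MAPK pathway output (18 genes, median -0.13, adjusted p = 0.107) included the feedback inhibitor SPRY4 at -0.45 ± 0.22 and ETV1 at -0.61 ± 0.28. Without control replicate 4, ID1 measured -0.30 and ETV1 -0.40. Camera called the MAPK list without control replicate 4 (0.0478) and with the mean of all probe sets (0.0335), but not with an estimated correlation (adjusted p = 0.416), and its median was -0.01 after quantile normalization again. Heat shock genes (10 genes, median -0.08, adjusted p = 0.210), oxidative phosphorylation (31 genes, median -0.00, adjusted p = 0.605) and ribosomal proteins (28 genes, median -0.03, adjusted p = 0.194) included HSPA4 at -0.28 ± 0.11, UQCRC2 at -0.22 ± 0.11 and RPL3 at -0.18 ± 0.10, the last -0.11 without anti-miR-182 replicate 1. Ribosomal proteins were called after cyclic loess (adjusted p = 0.0181), and with the mean of all probe sets both they and heat shock genes were called, but not with an estimated correlation (adjusted p = 0.664 and 0.416). In these 8 lists 0 members passed when adjusted over the list alone. The medians of apoptosis, adhesion, TGF-beta response, hypoxia, stress and oxidative phosphorylation genes changed sign between scalings, for TGF-beta response from -0.10 with median centring to 0.18 with quantile normalization again. With an estimated correlation 0 of the 22 lists passed.

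Several array measures moved with the treatment. Dim probe sets read higher and bright ones lower on the treated arrays: the median difference was 0.11 for the 17797 probe sets with a mean log2 intensity below 4, 0.19 between 4 and 5, -0.24 between 7 and 8, and -0.05 above 10. The fall of bright ones depended on the setting. Over all probe sets brighter than the median it was -0.10, but 0.01 without anti-miR-182 replicate 1 and 0.03 after quantile normalization again. Leaving out any other single array kept it below 0. The 75th percentile of log2 intensity was 7.02 ± 0.02 (SD, n = 4) in the controls and 6.79 ± 0.17 in the treated arrays, with no overlap (two-sided exact permutation p = 0.0286, adjusted p = 0.0762 over 8 measures). Anti-miR-182 replicate 1 stood lowest in it, at 6.54, against 6.84 to 6.91 on the other treated arrays. Hybridization controls of bacterial origin, added to the sample rather than made by it, were 1.33-fold higher on the treated arrays, also without overlap (exact p = 0.0286, adjusted p = 0.0762). The log2 ratio of 3 prime to 5 prime signal of ACTB, which rises with RNA degradation, was 2.26 ± 0.29 in the controls and 2.57 ± 0.16 in the treated arrays (exact p = 0.143), and that of GAPDH 0.28 ± 0.08 and 0.39 ± 0.13 (exact p = 0.229). The GAPDH ratio was highest in anti-miR-182 replicate 1, at 0.55, against 0.23 to 0.41 on the other treated arrays. The signal of the Alu repeat control was 14.49 ± 0.13 and 14.18 ± 0.13 (exact p = 0.0571), and that of the control for large-subunit ribosomal RNA 12.06 ± 0.29 and 12.49 ± 0.12 (exact p = 0.0571), higher in the treated group where RNA45SN5 was lower.

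**Figure D4:**
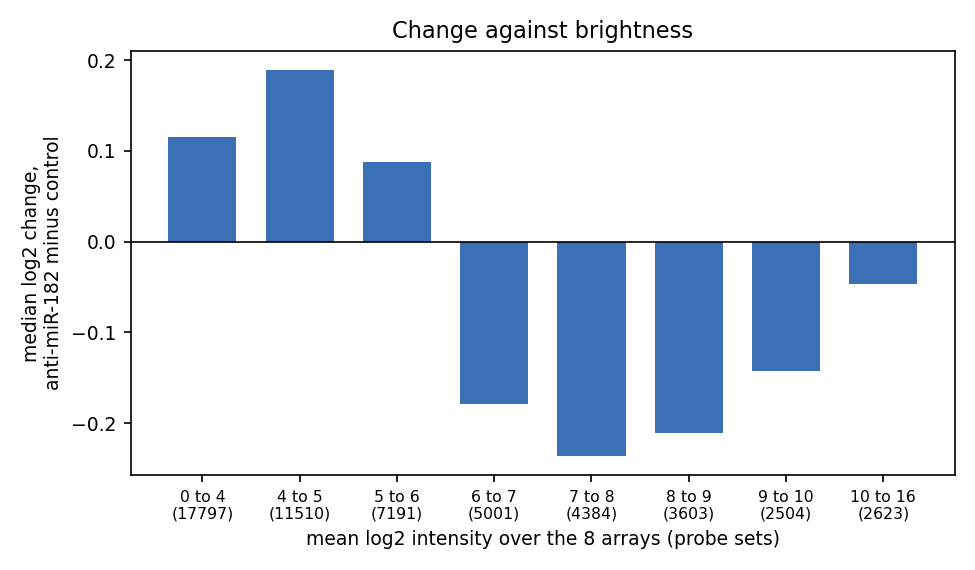
Median log2 difference (anti-miR-182 minus control, vertical axis) of probe sets grouped by mean log2 intensity over the 8 arrays (horizontal axis, number of probe sets in brackets). Bars are above 0 for the dim groups (0.19 between 4 and 5) and below 0 for brighter ones (-0.24 between 7 and 8). Over all probe sets brighter than the median, the median difference was -0.10 on all arrays but 0.01 without anti-miR-182 replicate 1.

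The first principal component of the 5000 most variable probe sets held 49.5% of the variance and placed all 4 treated arrays above all controls (two-sided exact permutation p = 0.0286). Control replicates 2 and 4 lay farthest out on it, at -40.7 and -76.1, against 17.4 to 34.7 for the treated arrays and -2.05 and 3.16 for the remaining controls. Correlations between arrays over all probe sets were 0.974 to 0.990 among controls, 0.964 to 0.992 among treated arrays and 0.944 to 0.990 between groups. In control replicate 4, 100 genes lay at least 4-fold above every other array, against 0 to 11 on the others.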

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

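The lists that tested explanations for control replicate 4 were chosen after that array was noticed and before their values were seen. The search for a single array far from the rest of its group had been set beforehand and covered 278 groups of 4 values. Chance places an array that far out in about 1 of 20 groups, or 13.9 here, and 16 were found, so the number is close to chance. The figures given are the gap to the nearest other array of the group divided by the group's range.

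Among the named genes, control replicate 4 was highest for ID1 (0.904), an inhibitor of DNA binding, and CREB1 (0.860), and lowest for CCND2 (0.855). Control replicate 3 was lowest for SEL1L (0.898), and control replicate 1 lowest for CLEC14A (0.904 of the range, at 3.81 against 4.01 to 4.03). Anti-miR-182 replicate 1 was highest for VWF (0.904), SLC4A1 (0.865), IRF4 (0.863) and RPL27 (0.858), and lowest for BCL2 (0.916) and HSPB1 (0.830), a small heat shock protein. Anti-miR-182 replicate 2 was lowest for KRT19 (0.918). Of the lists, cholesterol synthesis was highest in control replicate 3 (0.884), and fibroblast and stellate cell markers were highest in control replicate 4 (0.961). The control for large-subunit ribosomal RNA was lowest in anti-miR-182 replicate 3 (0.875).

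Control replicate 4 had 100 genes at least 4-fold above every other array (0.899 for that count among the controls), led by the gap junction protein GJA1, 5.38 log2 units above the next array, the noncoding RNA DNM3OS (5.16), the matrix proteoglycan LUM (4.80), osteopontin SPP1 (4.65), SCEL (4.50), SPARCL1 (4.33) and collagen COL1A2 (4.31). For fibroblasts of the host as a source, 26 further fibroblast genes exceeded the median of the other arrays by a median of 0.24. That is under the 0.3 set beforehand as too low, so the bound as written counts against fibroblasts. It lies under 0.3 by less than the genes' spread of 0.62, a margin that was not part of the bound. As 8 of the genes exceeded the median of the other arrays by 1 or more, fibroblasts were not excluded. For a sample of another cell line, a median of 13 cancer-testis antigens more than 1 below the lowest other array had been predicted. It was 8.97, within the 8.29 to 8.99 of the other arrays, so the bound set beforehand counts against that explanation. The value lay within their SD of 0.24 of the upper end, and the mean, 8.65, lay above the 8.06 to 8.46 of the others. Another cell line was therefore not excluded. A change of state in the tumour cells of that metastasis was not tested.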

How the results depend on the processing

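Cyclic loess, leaving out 2 arrays together, ranks among random lists and all alternatives of the unadjusted counts were chosen after seeing the data. The counts of 0 probe sets and 0 genes at an adjusted p under 0.05 held under every alternative run except array weights (389 probe sets, 124 genes). Those 124 genes lay just under the threshold, with adjusted p from 0.0480 to 0.04998 in limma. The cause was not tested. Anti-miR-182 replicate 1 had the lowest weight, 0.221, but leaving it out gave 0 probe sets at 0.05 and 0 at 0.1. At an adjusted p under 0.1, 0 probe sets passed, against 8831 with array weights, 2182 without control replicate 3, 1117 with median centring and 713 with quantile normalization again. At an unadjusted p under 0.05, probe sets numbered 6303 and genes 2507 among those brighter than the median, where fewer were tested; genes numbered 2797 after cyclic loess, and the cause was not tested. Leaving out each array gave 8883 (without control replicate 2) to 13690 probe sets and 3027 (without control replicate 2) to 4920 genes. Lists called numbered 4, against 0 with an estimated correlation, 9 with the mean of all probe sets, 9 among the outer 2.5% of random lists on either side, and 2 to 7 when leaving out each array (7 without control replicate 2, 2 without control replicate 3 or anti-miR-182 replicate 3); the cause was not tested. Hepatocyte markers passed in 16 of 17 settings, erythroid markers in 14, cell cycle genes in 12 and interferon genes in 10, each with its direction kept. Of 107 named genes, 104 kept their sign in every setting and 15 passed with array weights alone; 41 turned sign or moved by over 1.5 times when 1 array was left out, 17 of them without anti-miR-182 replicate 1 and 13 without control replicate 4. The replicate numbers did not pair the samples: same-numbered arrays deviated with correlations of -0.29 to -0.04. With the replicate block, 0 probe sets and 0 genes passed, 10531 probe sets had an unadjusted p under 0.05 and 6 lists were called. The test of miR-182 seed sites and its alternatives were not run. Quantile normalization fixes the percentiles of intensity, so no value is given for them there. Signal over background was not assessed, which limits what dim genes can show.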

Other observations

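The tests of host liver RNA and of degraded RNA, the comparison within arrays with genes of other tissues, and the split counts of probe sets and genes past an adjusted p were chosen only after the result was seen. Transcripts kept in the nucleus had a median of -0.65 over 18 measured, with 7 lower and 3 higher at an unadjusted p under 0.05, and the mean over the list per array overlapped between groups (exact permutation p = 0.0571). CCNL2, a cyclin of splicing, measured -1.09 ± 0.27 (SE, n = 4 per group), NKTR -1.23 ± 0.33 and the glycosyltransferase OGT -0.88 ± 0.25, each with all 4 treated arrays below the controls. MIAT (0.54 ± 0.16), PVT1 (0.46 ± 0.14) and MEG3 (0.30 ± 0.13) were the 3 higher ones. MALAT1 (-1.31 ± 0.37) and FTX (-2.23 ± 0.36), chosen after their values were seen, prompted the list and are not in it. None of these passed limma's adjusted threshold of 0.05 in the unweighted fit.

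Antithrombin SERPINC1 measured 1.36 ± 0.21, ceruloplasmin CP 1.39 ± 0.26 and IGF1 1.52 ± 0.36. These 3 were chosen after their values were seen, and none passed limma's adjusted threshold in the unweighted fit. Of 38 further liver genes, 19 were higher and 0 lower at an unadjusted p under 0.05 (median 0.33), and of 42 further host blood and sinusoid genes 20 were higher and 0 lower (median 0.31). Further fibroblast genes had a median of 0.02 over 26, and cancer-testis antigens 0.01 over 13. Control replicate 2 stood at least 4-fold above all other arrays for 11 genes, among them the pericyte gene RGS5, the phosphatase PTPRZ1, the receptor ERBB3 and the neural crest factor SOX8, named after their values were seen.

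The hepatocyte list was higher on the treated arrays with camera's preset correlation, a call lost at an adjusted p = 0.416 with an estimated correlation. Mean brightness alone did not account for the whole difference: the list's median stood at percentile 99.98 of lists of like brightness. The list also passed camera with the preset correlation after cyclic loess (adjusted p = 0.000832), though its median fell from 0.37 to 0.22 there. Both values met the bound set beforehand for counting against dim probe sets as the explanation. The same ranking placed genes of other tissues nearly as high, so it cannot exclude dim probe sets of silent genes reading higher. Genes silent in melanoma and liver reading higher as well remains open and may account for much of it: genes of other tissues stood at percentile 99.15, and measured within each array the hepatocyte list exceeded them by only 0.16 more on the treated arrays (exact p = 0.0286, adjusted p = 0.171 over 6 lists). A larger share of host liver RNA, or liver genes switched on in the tumour cells alone, cannot be told apart from it, since the further host lists stood at percentile 99.27 or above but differed from the genes of other tissues by only 0.02 and 0.03 (exact permutation p = 0.771 and 0.200), which makes the bound set beforehand for the tumour-cell explanation wrong. Whether human probes read mouse RNA was not tested, and an effect of anti-miR-182 on the tumour stays open as well.

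Lower long noncoding RNA on the treated arrays was a pattern taken from the genes with the smallest p, and it did not hold for the class. The 2657 genes of that class had a median of 0.19 and stood at percentile 100 of protein-coding lists of like brightness. The class was not lower, so brightness as the cause of a lower class did not arise. The class thus lay opposite to the pattern. For the nuclear-retained list alone, less nuclear or unspliced RNA remains a candidate explanation, with its median at percentile 0 of lists of like brightness. More degraded RNA in the treated metastases cannot be told apart from this: the ACTB ratio was higher by 0.31, with overlapping arrays.

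Over the 35 splits of the 8 arrays into 4 and 4, the real split had the most probe sets at an unadjusted p under 0.05. It gave 13530, against at most 7731 in the others. So few splits reaching that count, under the share of 0.05 set beforehand, makes chance less likely. Rank 1 of 35 is the best these splits can give, so chance is not excluded. Array-wide measures also differed between the groups, so the count does not number independent changes. For the probe sets and genes past an adjusted p of 0.05, all 35 splits gave as many, 0, with 0 the highest of the others. For gene lists, 15 of the 35 splits called at least the 4 of the real split and the highest of the others called 8, so chance cannot be excluded for the number of lists called.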
